A study of Homo sapiens with 8 samples.

How the data were processed

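RNA was measured by sequencing of total-RNA libraries from primary human osteoblasts, the bone-forming cells, cultured with the ligand Wnt3a or with Wnt3a and all-trans retinoic acid (ATRA). The series has 8 libraries, 4 per treatment. Each title gives the treatment and a number from 1 to 4, and the series design text names 4 healthy donors. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a stranded total-RNA kit in which another polymerase mix replaced the one of the final PCR. ATRA dose and treatment time are not given in the sources used here.

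The authors deposited a table of estimated counts and a table of TPM (a length-corrected measure of a transcript's share of the library), each with 1 row per gene symbol. Per the submitters' processing notes, reads were quantified with kallisto against hg38/GRCh38; the kallisto version and the transcript annotation are not given in the sources used here. The deposited estimated counts are whole numbers that sum to between 27438160 and 46856410 per library, and they entered the tests as deposited. The deposited TPM values sum to between 979244 and 981930 per library. Kallisto assigns a read that matches several transcripts in proportion to their estimated abundance, so genes with near-identical copies share reads. Each table also holds 8 columns of values whose names match no sample of the series, and these were not used. A row without a gene name held 0.198% to 0.284% of a library's counts and was left out of library sizes and tests. XIST and Y-linked genes were left out of every table, which left 28545 of 28902 rows.

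The comparison was Wnt3a+ATRA against Wnt3a. Before the data were examined, the main test, its alternatives, 27 gene lists with 985 symbols and the rule for the genes named were fixed. The main test was edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default expression filter on the group, a robust quasi-likelihood fit without a block and a two-sided test. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The filter kept 14052 genes. Standard errors (SE) of edgeR values are the absolute log2 fold change divided by the square root of the F statistic of its test. The ratio of a change to this SE does not rank the p-values. Mean ± SD values are TPM over 4 libraries per group unless stated. Log2 ratios of single pairs are differences of log2 CPM (counts scaled to library size) with a prior count of 2. Without a block, p-values measure the change against the spread between donors. In fits with the sample number as a block, they measure it against how the difference between treatments varied between donors.

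The fit with the sample number as a block was planned as an alternative. The numbers pair the libraries. Deviations from the group means correlated at 0.59, 0.64, 0.58 and 0.69 between the same-numbered libraries 1, 2, 3 and 4 across genes, and the design text names as many donors as there are numbers. The fit with the block is called the paired fit here, and "rose" and "fell" refer to its calls unless another fit is named. The coefficient of biological variation was 35.1% without the block and 15.7% with it. No pair of libraries agreed within counting noise, so each counts as a separate sample, and the replicates are donors. Leaving out each pair in turn was planned. The fit without pair 2, over 14033 genes, is described in more detail than the others, a choice made after retinoid-response genes were seen at high levels in the library labelled Wnt3a 2.

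Lists were tested with camera (limma 3.58.1) on log2 CPM at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists that had at least 5 genes tested. Of the 985 symbols, 982 matched a row. Camera with an estimated correlation and fry were run beside it. Other alternatives were DESeq2 1.42.0, limma-voom with quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), DESeq2 size factors, library size alone, 2 other filters, a fold threshold, removal of 16 mitochondrial, ribosomal and small RNA rows, and each library left out.

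Named are the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a mean log2 CPM of at least 1 and the same direction in all 4 pairs, taken from the paired fit where the main fit gave fewer. Also named are up to 4 members per list with a call, and 31 genes of the retinoid, Wnt, Notch, osteoblast and niche systems whatever their values. A few genes that the rule names are not reported here. Genes with more than 50% of their longest transcript shared with another gene at 98% identity or more over at least 100 bases (BLAST 2.17.0 on GENCODE transcripts), pseudogenes and small RNAs were left out of the first part. Coordinates are from the RefSeq annotation of GRCh38, 1-based. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

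The steps were tested on simulated counts with the means, library sizes, donor differences and dispersions of these libraries and 200 genes changed by 1.5-, 2- or 4-fold. Each simulated change was the same in every donor, and a single set of counts was drawn. The shares below therefore do not describe genes whose response differs between donors, as in pair 2. Over 13842 genes, the fit without a block recovered 3.03%, 43.8% and 71.4% of genes changed by 1.5-, 2- and 4-fold, with 0 false calls. The paired fit recovered 47.0%, 84.4% and 92.1%, and 10.6% of its calls were false. Without pair 2, over 13771 genes, it recovered 37.9%, 79.4% and 92.1%, and 15.8% of its calls were false. Both shares of false calls exceed the threshold of 0.05.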

Results

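Gene expression was measured in primary human osteoblasts that received Wnt3a, a ligand that activates beta-catenin signalling, alone or with ATRA, the ligand of the retinoic acid receptors. The series title places the work in the marrow niche of myeloid malignancies. The comparison asks which transcripts ATRA changes in osteoblasts exposed to Wnt3a. Library depth was 35795100 ± 8217440 estimated counts with Wnt3a and 32107700 ± 2566100 with Wnt3a+ATRA (SD, n = 4 each), with a range of 27438160 to 46856410. Between 15744 and 17350 genes had a count. Fibronectin (FN1) alone took 7.45% ± 1.99 of counts with Wnt3a and 7.25% ± 1.94 with Wnt3a+ATRA, and mitochondrial mRNAs took 6.09% ± 1.06 and 6.20% ± 0.80.

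With ATRA, the retinoic acid binding protein CRABP2, the adhesion molecule ICAM1, the cytokines CCL26 and IL1B and the receptor NOTCH2 rose. The Wnt feedback gene AXIN2, the Notch ligand JAG1, the transcription factors TWIST1 and SNAI2, the interleukin IL6, osteoprotegerin (TNFRSF11B) and the sterol enzymes MSMO1 and HMGCS1 fell. These calls come from the paired fit, which takes the donor out of the comparison, and those of CRABP2, IL1B, NOTCH2, AXIN2, IL6 and HMGCS1 were lost in at least 1 fit that left out a pair. With edgeR's quasi-likelihood test and no block, 0 of 14052 genes passed an adjusted p of 0.05. In that fit 687 genes had an unadjusted p under 0.05, or 4.89%, and the smallest adjusted p was 0.0792, for NAB2 and MYO1E, both named after their values were seen. Without a block, DESeq2 called 114 genes, 82 of them higher, and limma-voom and limma on log2(TPM + 1) called 0. The paired edgeR fit called 400 genes, 203 higher and 197 lower with ATRA. Of these, 399 changed in the same direction in all 4 pairs, and 90 had more than a 2-fold change. With the same block, DESeq2 called 814 genes, 461 of them higher, and limma on log2(TPM + 1) called 222, 139 of them higher. Libraries of the same number correlated at 0.961 to 0.984, against 0.937 to 0.961 between libraries of the same treatment.

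CYP26B1, RARB and DHRS3, genes of the retinoid response, were higher in a single Wnt3a library than in the others. CYP26B1, an enzyme that degrades retinoic acid (chromosome 2, 72129238 to 72147862), was at 0.736, 2.85 and 2.15 TPM in Wnt3a libraries 1, 3 and 4 and at 108 to 222 TPM in the 4 ATRA libraries. The library labelled Wnt3a 2 had 57.0 TPM. The retinoic acid receptor RARB (chromosome 3, 24829321 to 25597932) was at 3.05 ± 0.50 TPM (SD, n = 3) in Wnt3a libraries 1, 3 and 4, at 46.9 TPM in the library labelled Wnt3a 2 and at 34.1 to 69.5 TPM with ATRA. The retinal reductase DHRS3 (chromosome 1, 12567910 to 12618210) was at 9.84 ± 3.56 TPM (SD, n = 3) in the same 3 libraries, at 178 TPM in the library labelled Wnt3a 2 and at 239 to 286 TPM with ATRA. All 3 genes were higher with ATRA in 4 of 4 pairs, but in the paired fit over all pairs their adjusted p-values from edgeR were 0.284, 0.315 and 0.351.

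**Figure D1:**
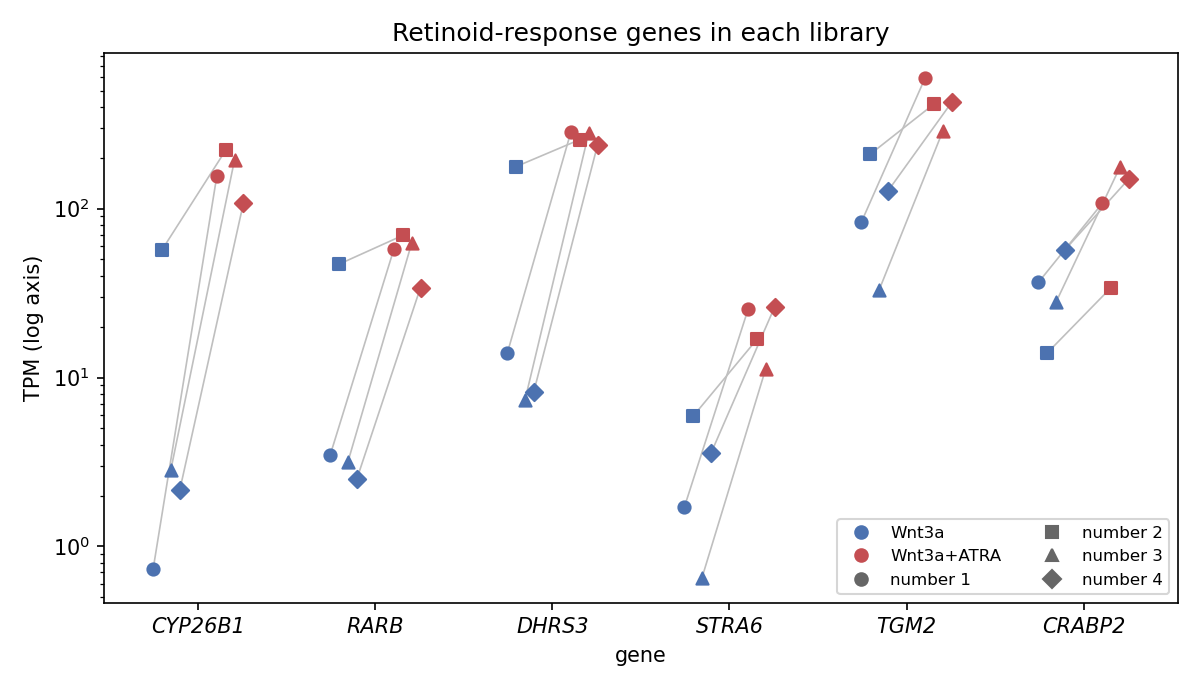
TPM on a log axis of 6 retinoid-response genes in each of the 8 libraries, with blue points for Wnt3a, red points for Wnt3a+ATRA, a symbol per sample number and a grey line per pair. CYP26B1, RARB and DHRS3 were low in Wnt3a libraries 1, 3 and 4, while the library labelled Wnt3a 2 had 57.0, 46.9 and 178 TPM.

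Without pair 2, the paired edgeR fit gave RARB a log2 fold change of 3.96 ± 0.16 (SE, adjusted p = 5.4e-09), DHRS3 4.86 ± 0.23 (adjusted p = 8.85e-05) and the retinol transporter STRA6 3.07 ± 0.34 (adjusted p = 0.00134). CYP26B1 at 6.85 ± 0.68 and the transglutaminase TGM2 at 2.30 ± 0.34 did not pass in this fit, with adjusted p-values of 0.103 and 0.112. Without a block, CYP26B1 passed in edgeR when the library labelled Wnt3a 2 was left out (6.99, adjusted p = 0.00481). It also passed without both libraries numbered 2 (6.86, adjusted p = 0.0317), a fit chosen after the data were seen. TGM2 passed in neither. CYP26A1, the other main retinoic acid hydroxylase, was below the filter, with 0, 5, 0 and 0 counts in Wnt3a libraries 1 to 4 and 61, 38, 46 and 1 counts with ATRA, and 33.6% of its transcript is shared with another annotation. With all pairs, the retinoic acid binding protein CRABP2 rose from 33.9 ± 18.1 to 117 ± 62.0 TPM (log2 fold change 1.81 ± 0.26, edgeR adjusted p = 0.0434), and the call was lost without pair 1, 2 or 4. Of 36 list members tested, 4 rose and 0 fell in the paired fit, namely ICAM1, CRABP2, ELOVL6 (lost without pair 4) and ETS1 (lost without pair 1, 3 or 4), and 6 rose when adjusted over the list alone. Without pair 2, 11 rose, or 15 when adjusted over the list alone with 1 that fell, among them the corepressor NRIP1 (2.71 ± 0.14) and SMAD3 (1.55 ± 0.10), both named after their values were seen. Camera placed the list above other genes, with an adjusted p of 3.23e-06 without the block and 9.92e-05 with it. With an estimated correlation the adjusted p was 0.634 and 0.769.

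The 10 genes with the largest rise included a water and glycerol channel, AQP7. It had a log2 fold change of 2.77 ± 0.40 from 1.04 ± 0.78 to 5.98 ± 3.68 TPM (edgeR paired fit, adjusted p = 0.00307). The eotaxin CCL26 rose from 4.41 ± 2.14 to 21.8 ± 2.45 TPM (2.40 ± 0.33, adjusted p = 0.00228), and the urokinase PLAU from 51.1 ± 14.3 to 204 ± 85.3 TPM (1.96 ± 0.24, adjusted p = 0.0334). The adhesion molecule ICAM1 rose by 1.83 ± 0.17 and the interleukin IL1B by 2.23 ± 0.29, on the log2 scale. The Wnt receptor FZD5, the sulfatase ARSI, the transcription factor TOX2 and the cystatin CST2 complete the 10 with CRABP2. Their log2 fold changes were 2.01 for FZD5, 2.63 for ARSI, 1.84 for TOX2 and 1.82 for CST2.

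The 10 genes with the largest fall included GAS1 and interleukin 6. GAS1, a membrane protein that binds Hedgehog ligands, fell from 47.1 ± 33.2 to 13.2 ± 11.01 TPM and had the smallest adjusted p of the paired edgeR fit (log2 fold change -1.84 ± 0.11, adjusted p = 1.73e-05). IL6 fell from 212 ± 156 to 75.2 ± 53.1 TPM (-1.54 ± 0.18, adjusted p = 0.00984). The phosphatase DUSP10 fell from 21.6 ± 4.51 to 7.57 ± 0.43 TPM (-1.40 ± 0.14, adjusted p = 0.000628), and had an adjusted p of 0.0867 without the block. HEY2 had a log2 fold change of -2.16, CX3CL1 of -1.70, KCNE4 of -1.38, CAMKK1 of -1.31, MSC of -1.28, C3orf80 of -1.27 and C11orf87 of -1.26. Of these 20 genes, 13 stayed past the threshold whichever pair was left out. ARSI, IL6, PLAU, CX3CL1, C3orf80 and CRABP2 lost their call without at least 2 different pairs, and IL1B without pair 3.

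**Figure D2:**
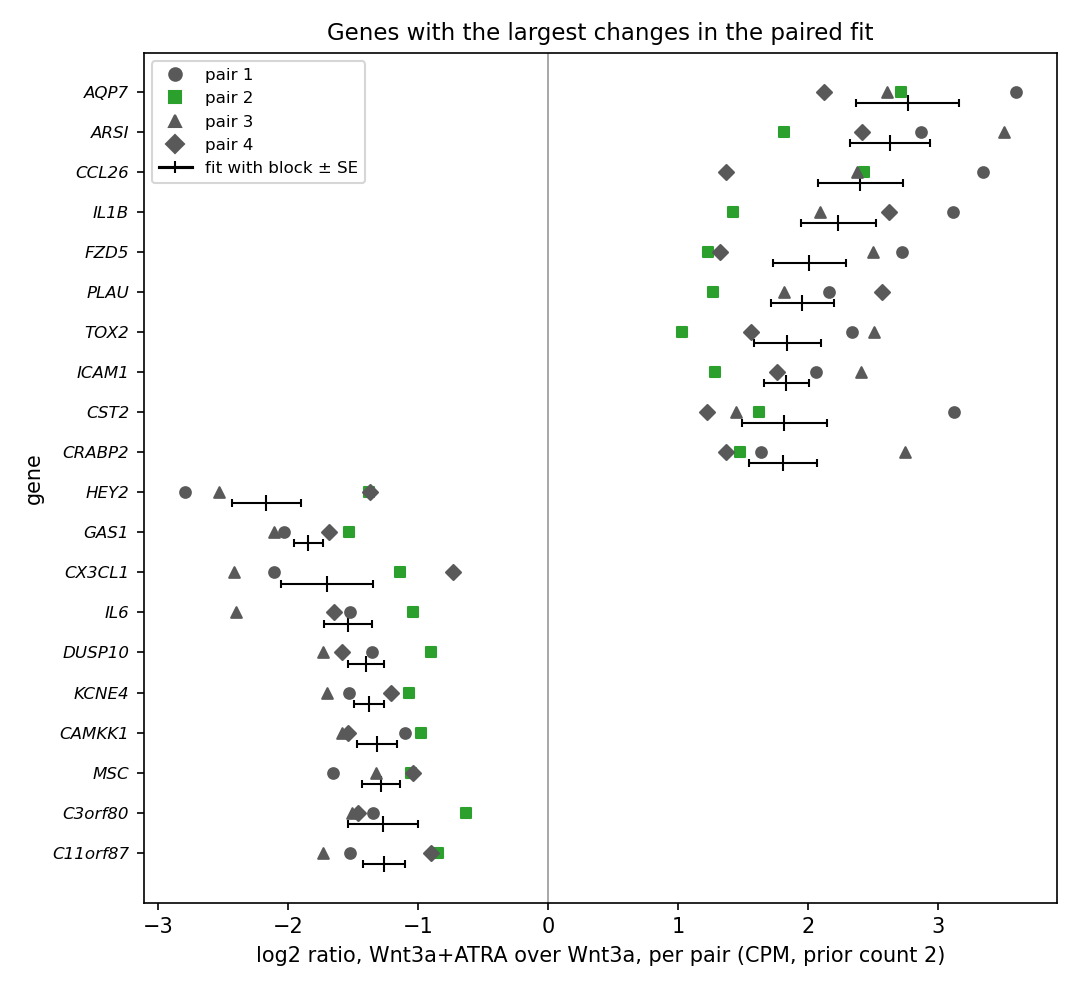
Log2 ratio of Wnt3a+ATRA over Wnt3a in each of the 4 pairs for the 10 genes with the largest rise and the 10 with the largest fall, with pair 2 in green, and the fitted log2 fold change of the paired fit with its SE as a black bar. The rule for naming these genes required every point to lie on the same side of 0. Fitted values run from AQP7 at 2.77 to HEY2 at -2.16.

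Wnt/beta-catenin target genes moved in both directions. AXIN2, the feedback inhibitor used as a readout of beta-catenin activity (chromosome 17, 65528563 to 65561648), fell from 5.64 ± 2.11 to 2.37 ± 0.28 TPM. Its log2 fold change was -1.05 ± 0.19 in the paired edgeR fit (adjusted p = 0.00949) and -1.13 ± 0.31 without the block (adjusted p = 0.612). The paired call was lost without pair 3, and 31% of the AXIN2 transcript is shared with another annotated gene. The mesenchymal transcription factors SNAI2 (-0.99 ± 0.12) and TWIST1 (-1.004 ± 0.13) and the osteoclast inhibitor osteoprotegerin, TNFRSF11B (-0.84 ± 0.11), also fell. By contrast, the TCF factor TCF7 rose from 12.02 ± 3.25 to 20.5 ± 4.43 TPM (0.73 ± 0.12, adjusted p = 0.00508), the cyclin CCND1 by 0.48 ± 0.08 (adjusted p = 0.00839, lost without pair 1) and the pseudoreceptor BAMBI by 1.28 ± 0.16 (adjusted p = 0.00122). The Wnt antagonist DKK1 had a log2 ratio of -1.36, -0.04, -1.42 and -1.12 in pairs 1 to 4. It passed the threshold without pair 2 (-1.30 ± 0.11, adjusted p = 8.73e-06) and not with it (adjusted p = 0.254). MYC stood at 39.1 ± 5.27 and 37.0 ± 2.97 TPM and CTNNB1, which encodes beta-catenin, at 234 ± 55.5 and 257 ± 68.9 TPM, with paired adjusted p-values of 0.972 and 0.274. LEF1 and NKD1 were under 2 TPM on average in both groups and did not pass. Of the 37 targets tested, 5 rose and 7 fell, or 8 and 9 when adjusted over the list alone, and camera gave an adjusted p of 0.810 in the paired fit.

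Among 51 Wnt pathway components, 2 rose and 5 fell, as many as when adjusted over the list alone. The receptors FZD1 (-0.66 ± 0.10) and FZD2 (-0.80 ± 0.15) fell, while FZD5 and the ligand WNT10B rose. WNT10B was at 0.37 ± 0.29 and 1.84 ± 1.30 TPM. The calls of FZD2 and WNT10B were lost in fits without pair 1 or 4 and without pair 3, respectively. The list's camera adjusted p was 0.663.

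In the Notch pathway, the ligand JAG1 fell and the receptor NOTCH2 rose. JAG1, a Notch ligand (chromosome 20, 10637684 to 10673999), fell from 65.3 ± 24.8 to 47.6 ± 17.9 TPM. In pairs 1 to 4 its log2 ratios were -0.59, -0.32, -0.55 and -0.59, with a paired log2 fold change of -0.51 ± 0.08 (edgeR adjusted p = 0.00403) that held without any single pair. Without the block the value was -0.51 ± 0.35 (adjusted p = 1.00). NOTCH2 (chromosome 1, 119911553 to 120069662) rose from 111 ± 27.6 to 205 ± 23.6 TPM (0.90 ± 0.13, adjusted p = 0.0141). Its call was lost without pair 3 or 4, and 8.53% of its transcript is shared with another annotated gene. The target gene HEY2 fell from 7.28 ± 5.63 to 1.36 ± 0.74 TPM (adjusted p = 0.00153), and the Notch inhibitor NUMBL fell by 0.49 on the log2 scale, a call lost without pair 1, 2 or 4. HES1 was at 8.30 ± 6.53 and 15.1 ± 6.85 TPM and did not pass (adjusted p = 0.314), and HEY1 was below the filter. The list member HEYL, named after its values were seen, was higher in 4 of 4 pairs. It did not pass over all pairs (1.47 ± 0.39, adjusted p = 0.165) but did without pair 2 (1.95 ± 0.19, adjusted p = 2.42e-05). Of 35 members, 1 rose and 4 fell, or 3 and 8 when adjusted over the list alone, and camera gave an adjusted p of 0.160.

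**Figure D3:**
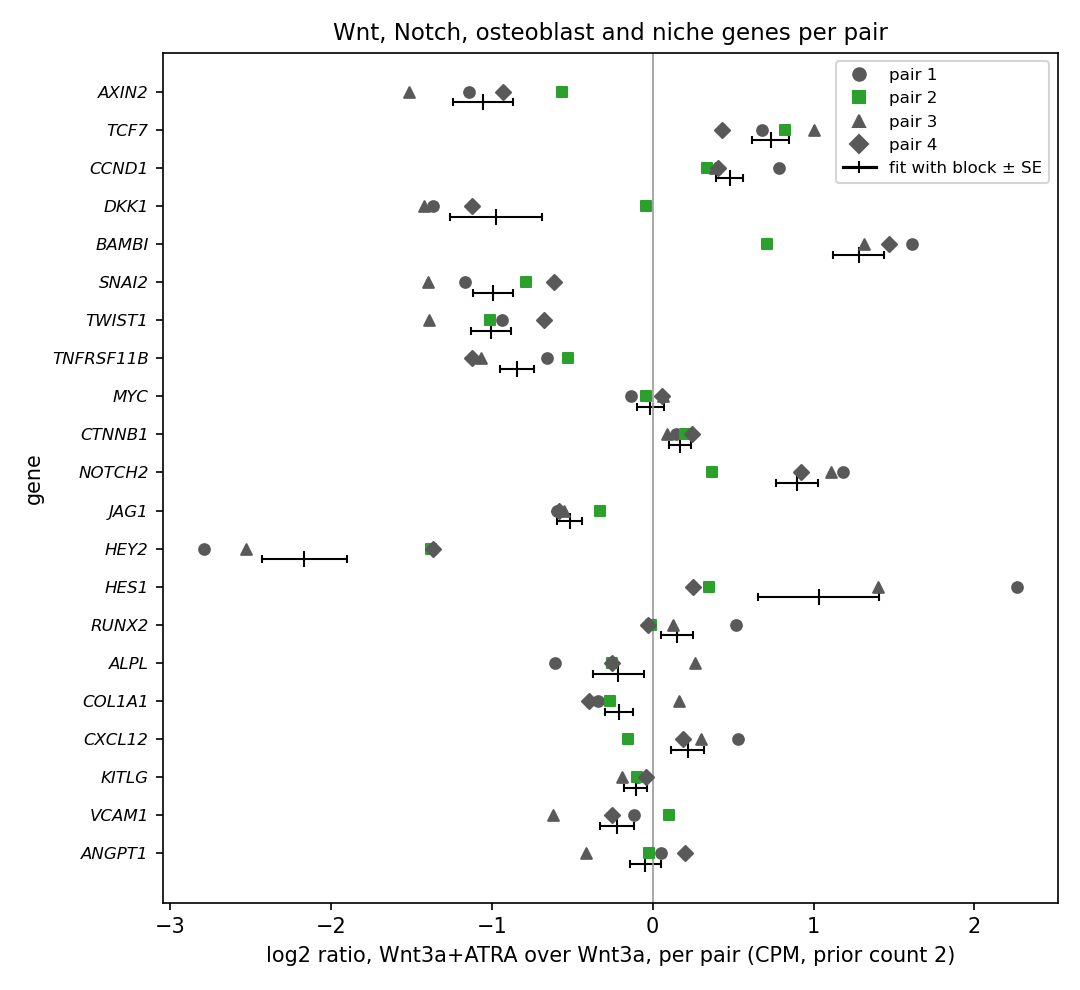
Log2 ratio of Wnt3a+ATRA over Wnt3a per pair for Wnt, Notch, osteoblast and niche genes, with pair 2 in green, and the paired fit with its SE as a black bar. AXIN2 and JAG1 lie below 0 in all 4 pairs, with fitted values of -1.05 and -0.51, while MYC, RUNX2 and ANGPT1 lie on both sides of 0.

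Few osteoblast and matrix genes passed in the paired edgeR fit. RUNX2, the osteoblast master regulator, was at 21.4 ± 5.66 and 25.6 ± 12.1 TPM, alkaline phosphatase ALPL at 8.56 ± 3.43 and 7.23 ± 3.50 TPM, and COL1A1 at 8280 ± 3177 and 7165 ± 2545 TPM. Their paired adjusted p-values were 0.576, 0.642 and 0.322, and that of SPP1 was 0.508. SP7 had at most 7 counts in any library. Osteocalcin, BGLAP, was at 12.6 ± 6.78 and 50.1 ± 23.6 TPM, but its log2 ratio was 2.88, 1.38, 3.54 and 0.07 in pairs 1 to 4. It did not pass (adjusted p = 0.435), and 39.8% of its transcript is shared with a readthrough annotation. Of 45 osteoblast and bone matrix genes, the gap junction gene GJA1 was the only call of the paired fit (0.40 ± 0.08, adjusted p = 0.0169, lost without pair 1 or 4), also when adjusted over the list alone. Without pair 2, 3 of 44 rose and 0 fell. Among them were DLX3 (1.82 ± 0.18, adjusted p = 4.14e-05) and the vitamin D receptor VDR (1.34 ± 0.16, adjusted p = 0.000657), both named after their values were seen. Among 58 collagens and matrix assembly genes, the lysyl oxidase LOXL4 rose from 36.7 ± 16.9 to 69.3 ± 28.3 TPM and thrombospondin THBS1 fell from 3475 ± 747 to 2046 ± 139 TPM. Among 45 matrix proteases and inhibitors, PLAU and the tissue plasminogen activator PLAT rose and ADAMTS6 fell. Adjusted over the list alone, 1 rose and 3 fell in the matrix assembly list and 5 rose and 3 fell in the protease list. Camera adjusted p-values of these 3 lists in the paired fit were 0.663, 0.0916 and 0.949, while fry's test for changes in either direction gave 0.0190, 0.00587 and 0.0122. That fry test passed 19 of the 26 lists in this fit, so it does not set these 3 apart.

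Factors by which stromal cells act on blood stem cells were mostly without a call. CXCL12 was at 230 ± 91.7 and 271 ± 125 TPM, KITLG at 39.6 ± 5.35 and 37.4 ± 4.6, VCAM1 at 358 ± 224 and 322 ± 234, and ANGPT1 at 51.4 ± 4.67 and 51.0 ± 13.8 TPM. Paired edgeR adjusted p-values were 0.370, 0.604, 0.392 and 0.914. Of 43 niche factors, NES rose and IL6, ANGPTL2 and EBF1 fell, or 1 and 4 when adjusted over the list alone. NES had an adjusted p of 0.0499 and passed in no fit that left out a pair, and the calls were lost without pair 1, 2 or 4 for ANGPTL2 and without pair 1 or 4 for EBF1 and IL6. RANKL, the osteoclast differentiation factor TNFSF11, was at 1.06 to 1.75 TPM in 3 Wnt3a libraries and at 0.596 to 1.95 TPM in 3 ATRA libraries, while both libraries numbered 2 stood higher, at 38.7 and 29.3 TPM, and its adjusted p was 0.890. Among 15 osteoclast regulators, EFNB1 rose from 18.01 ± 0.75 to 28.6 ± 3.49 TPM (adjusted p = 0.00445) and CXCL1 fell (adjusted p = 0.0168, lost without pair 1), or 3 and 3 when adjusted over the list alone. Of 33 cytokines and chemokines, 3 rose and 4 fell, or 4 and 5 when adjusted over the list alone. CCL26 and IL1B were among the first, CX3CL1 and TNFAIP3, an inhibitor of NF-kB signalling (lost without pair 4), among the second. Of 54 interferon-stimulated genes, 1 rose, GBP1 (0.76 ± 0.12), and 2 fell, among them IFI44L (-0.76 ± 0.12), or 2 and 4 when adjusted over the list alone. None of these 4 lists passed in the paired camera test, with an adjusted p of 0.663 for niche factors, osteoclast regulators and interferon-stimulated genes and of 0.936 for cytokines.

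Besides the retinoid list, 4 lists stood apart from other genes in the paired camera test at the preset correlation, and none did with an estimated correlation, where the smallest adjusted p was 0.225. Cholesterol and fatty acid synthesis genes lay lower (adjusted p = 4.21e-05 with the block, 0.000168 without; estimated correlation, adjusted p = 0.225). Of 33 tested, 6 fell and 2 rose, or 17 and 3 when adjusted over the list alone. Those that fell included the sterol enzymes MSMO1, from 84.3 ± 23.4 to 57.6 ± 4.37 TPM, and HMGCS1 (lost without pair 4), and the sterol sensor INSIG1 (-0.82 ± 0.12). HOX genes lay lower (adjusted p = 9.92e-05 with the block, 0.00638 without; estimated correlation, adjusted p = 0.225). HOXA9 fell from 29.04 ± 5.15 to 17.5 ± 3.97 TPM (-0.73 ± 0.13, adjusted p = 0.00767) and was the only call among 23, with 3 lower when adjusted over the list alone. TGF-beta and BMP pathway genes lay lower with the block (adjusted p = 0.00512) and not without it (0.0542), and with an estimated correlation the adjusted p was 0.424. The BMP antagonist GREM1 (-0.69 ± 0.10) fell, as did the BMP target genes ID3, a call lost without pair 1 or 2, and ID4, lost without pair 3 or 4. In all, 5 of 40 fell, against 12 lower and 2 higher when adjusted over the list alone. Cell cycle genes lay higher (adjusted p = 1.84e-05 with the block, 6.66e-05 without; estimated correlation, adjusted p = 0.769), with 54 of 62 fitted above 0 and 0 calls by edgeR over all genes or adjusted over the list alone. Their median log2 ratio was 0.48, 0.21, 0.04 and 0.01 in pairs 1 to 4. The cyclin-dependent kinase inhibitors CDKN1A, from 372 ± 100 to 233 ± 50.2 TPM (-0.64 ± 0.08, adjusted p = 0.00111), and CDKN1B (-0.48 ± 0.12, adjusted p = 0.0488) were the 2 calls among 32 p53 targets and cell cycle inhibitors, also when adjusted over the list alone, in a list with an adjusted p of 0.130. CDKN1B passed in no fit that left out a pair.

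Lists that bear on handling, stress and other cell types did not pass in camera over all pairs with the block. Among 29 immediate early and heat shock genes, KLF2 and DNAJB1 rose and KLF4 (-1.18 ± 0.16) and KLF6 (-1.06 ± 0.13) fell, with 3 rises and 5 falls in all, or 8 and 7 when adjusted over the list alone, and a camera adjusted p of 0.638. Of 31 stress response genes, HERPUD1 and DDIT4 rose, in calls lost without pair 1 or 4, and the cystine transporter SLC7A11 fell (adjusted p = 0.00311), and the list had an adjusted p of 0.663. Mitochondrial mRNAs had a median log2 fold change of 0.02 (adjusted p = 0.663), and of 13 histone genes H2AC6 fell, a call lost without pair 1 or 3 (adjusted p of the list 0.806). The adipocyte transcription factors CEBPA, at 1.24 ± 1.38 and 2.91 ± 2.08 TPM, and PPARG, at 2.70 ± 1.36 and 6.65 ± 3.96 TPM, rose, in calls lost without pair 1, 3 or 4. Sums of TPM were not tested, and the p-values given beside them are paired camera adjusted p-values of the list members tested. The summed TPM of adipocyte markers was 35.6 ± 12.1 and 40.9 ± 6.34 (camera adjusted p = 0.267). Summed TPM was 129 ± 58.3 and 134 ± 45.7 for chondrocyte markers (adjusted p = 0.663), 512 ± 130 and 496 ± 140 for smooth muscle and pericyte markers (0.663), and 13.95 ± 7.13 and 14.6 ± 8.44 for endothelial markers (0.806). Myeloid and lymphoid markers summed to 143 ± 55.3 and 144 ± 36.2 TPM, mostly from CD68 at 117 TPM. Their list had a paired camera adjusted p of 0.128, and of 0.769 with an estimated correlation. At the preset correlation it lay higher in the paired fits without pair 4 (0.0345) and with 1 CPM in 4 libraries (0.0225). Fibroblast markers summed to 1618 ± 415 and 1623 ± 522 TPM (0.254). No erythroid marker was above 1.39 TPM in any library, and that list was not tested. In 6 of the 26 lists, among them the osteoblast list, the Wnt components and the cytokines, the median and the mean log2 fold change of the paired fit had opposite signs.

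Leaving out pair 2, the paired edgeR fit called 575 genes, 358 higher and 217 lower, or 62.3% higher against 50.8% over all pairs. Of these, 329 were also among the 400 calls over all pairs, each in the same direction. The fits without pair 1, 3 or 4 called 239, 368 and 257 genes, and 150 of the 400 passed in each of the 4 fits with a pair left out. Without the block, 29 genes passed when the library labelled Wnt3a 2 was left out and 1 when Wnt3a+ATRA 2 was. The 29 included CYP26B1, RARB and DHRS3, which were high in the library left out.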

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

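Of the tests in this part, those on the library labelled Wnt3a 2 were chosen after its values were seen. A library was singled out where its gap to the nearest of the other 3 exceeded Dixon's 95% limit. Of 196 groups of 4 libraries looked at, 16 stood out, and chance gives about 1 in 20, or 9.8, for independent, normally distributed values. Most of these groups are TPM of genes that can vary together, many named for calls in the same libraries. A value above 0 also stands out wherever the other 3 are at 0, as for CYP26A1 and SP7. The 9.8 is therefore only a rough guide. The library labelled Wnt3a 2 held 7 of the 16. It was high in CYP26B1 (57.0 TPM), RARB (46.9), DHRS3 (178), ARSI (12), CEBPA (3.30), TNFSF11 (38.7) and CYP26A1 (0.35 TPM, from 5 counts). The other Wnt3a libraries lay at or under 2.85, 3.48, 13.9, 3.80, 0.667 and 1.75 TPM for the first 6 genes and at 0 for CYP26A1.

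Wnt3a+ATRA 4 stood out in 4 genes, low in HEY2 (0.261 TPM) and high in ELOVL6 (30.4), FZD1 (9.47) and ID3 (80.2). Wnt3a+ATRA 1 stood out in 3, with EBF1 at 19.9, HEY1 at 0.805 and SP7 at 0.0181 TPM. Wnt3a 3 was high in ID4 (21.9 TPM) and Wnt3a+ATRA 2 in TNFSF11 (29.3 TPM). Both libraries numbered 2 were thus high in TNFSF11.

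Several retinoid-response genes were high in the library labelled Wnt3a 2, and pair 2 showed a smaller response. CRABP2 was low in both libraries numbered 2, at 13.99 TPM with Wnt3a against 28.02 to 57.2 TPM in the others, and at 34.1 TPM with ATRA against 107 to 176 TPM. An exchange of labels between both libraries numbered 2 is argued against: of the genes called in the other 3 pairs, 88.2% changed in the same direction in pair 2. Whether RNA of 1 of the 4 ATRA libraries, mixed in at a single share, was the whole cause is not settled. Of 36 genes called at least 4-fold higher without pair 2, at least 55.6% had a level outside the range allowed by any single share (lowest bootstrap bound 36.1%). Without mixing, 25% would be outside if the library had the highest level in 1 of 4 genes. But these genes were called in part for low levels in Wnt3a libraries 1, 3 and 4, which also set the range. The percentage without mixing may therefore exceed 25%. With Wnt3a library 1, 3 or 4 in its place, 3 to 5 genes entered, too few to set that percentage. With the ATRA library numbered 2, the share needed was 68.0% for DHRS3, 66.1% for RARB, 25% for CYP26B1 and 26.5% for STRA6. The mean of the other Wnt3a libraries was taken as the level before mixing. The share was 407% for CRABP2, whose level in that ATRA library was below this mean. It was -3.38% for AQP7 and -4.87% for CCL26. These 2 genes were named for a large rise in the fit over all 4 pairs, which favours a low level in the library labelled Wnt3a 2. Their shares therefore do not weigh against mixing. A first test was not decisive. The interquartile range of the share needed with the ATRA library numbered 2 was 30.9 points (bootstrap 18.1 to 41.5, against a bound of 20). It was taken over genes low in the other Wnt3a libraries. RNA from a culture outside the series was not tested. Exposure of this culture to a retinoid, or a donor with retinoid activity of its own, may account for it. For genes that rose in the other pairs, pair 2 kept a median of 34% of the change there. For genes that fell, it kept 55.5%. For pairs 1, 3 and 4 the medians were 117%, 123% and 77.1% for rises and 103%, 94.2% and 72% for falls. A smaller change in pair 2 is part of the pattern itself, and mixing would also give it. It therefore favours none of these explanations. Exposure and donor activity cannot be told apart with 1 culture per donor and treatment.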

How the results depend on the processing

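Chosen after seeing the data were the fit without both libraries numbered 2 and no block, the further alternatives to the replicate block without pair 2, the fold threshold with the block, and fry with the block; the others were planned. Counts are given as all (higher, lower). Against 0 (0, 0) with edgeR and no block, the count stayed at 0 with DESeq2 size factors, library size alone, 1 CPM in 4 libraries, limma-voom, limma on TPM with either pseudocount or no filter, without mitochondrial, ribosomal and small RNA rows, and with a fold above 2. It was 114 (82, 32) with DESeq2 and 4 (2, 2) without a filter, namely MYO1E, PRKAG2, NAB2 and DUSP10, the first 3 named after their values were seen. Leaving out single libraries gave 0 to 29 (0 to 26, 0 to 3): 29 without the library labelled Wnt3a 2, 1 (MYO1E) without Wnt3a+ATRA 2 and 0 otherwise. Without both libraries numbered 2 and no block it was 11 (9, 2). With the replicate block it was 400 (203, 197). Further replicate block fits gave 814 (461, 353) with DESeq2, 492 (240, 252) without a filter, 412 (204, 208) with 1 CPM in 4 libraries, 391 (197, 194) with DESeq2 size factors, 222 (139, 83) with limma on log2(TPM + 1), and 90 (52, 38) with a fold above 2. Without pair 1, 2, 3 or 4 they gave 239 (121, 118), 575 (358, 217), 368 (162, 206) and 257 (122, 135). Without pair 2 the count was 708 (447, 261) with DESeq2, 567 (350, 217) with DESeq2 size factors, 740 (432, 308) without a filter, 631 (405, 226) with library size alone, and 227 (157, 70) with a fold above 2. Between the edgeR fits without and with the block, the coefficient of biological variation fell from 35.1% to 15.7%. The cause of the other differences was not tested, except that fewer libraries or genes enter some fits. Without the block, the median log2 fold change of all genes was -0.0161, and -0.0173 with DESeq2 size factors, -0.00581 with library size alone and -0.0190 with log2(TPM + 0.1). The share of higher calls in the paired fit was 50.8%, and 50.4% with DESeq2 size factors, 62.6% with limma on log2(TPM + 1) and 62.3% without pair 2.

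The number of lists past the threshold was 4 without the block and 5 with the replicate block, which added TGF-beta and BMP pathway genes. It was 7 with the block without pair 4, where interferon-stimulated genes and myeloid and lymphoid markers passed as well, both higher, and 6 with the block and 1 CPM in 4 libraries, with the myeloid and lymphoid markers again. It was also 6 with the block without pair 3, where collagens and matrix assembly genes lay lower (adjusted p = 0.00214), and with the block and no filter, where Notch pathway genes did (0.0478). It was 2 to 5 with single libraries left out, the lowest without the library labelled Wnt3a 2, where cell cycle and HOX genes no longer passed. HOX genes were also lost without Wnt3a 4, without Wnt3a+ATRA 1 and, with no block, without both libraries numbered 2. Cell cycle genes were also lost without Wnt3a+ATRA 3. Cytokines and chemokines passed, higher, without Wnt3a+ATRA 3 (0.0356), as did interferon-stimulated genes without Wnt3a 4 (9.83e-05). With an estimated correlation the number of lists was 0 in the fit without a block, with the replicate block and with the block without pair 2. Fry gave 0 without the block, 1 with it (cholesterol and fatty acid synthesis, adjusted p = 0.029) and 0 without pair 2, while its test for changes in either direction gave 4, 19 and 17 of 26 lists in these 3 fits. Over 37 values each, the main one included, the retinoid list passed in 31 (adjusted p from 4.84e-11 to 0.778), cholesterol in 32 (1.23e-05 to 0.721), cell cycle in 29 (1.09e-14 to 0.919), HOX genes in 27 (2.88e-05 to 0.780) and TGF-beta in 18 (0.00131 to 0.778), each in 1 direction. The list tests were not run on DESeq2 fits.

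For 149 named genes, 4894 values under 33 alternatives held 1397 newly past the threshold, 3497 on the same side and 0 that turned sign with a call; 43 changed sign without a call in either fit. AXIN2 passed in 12 of 33 alternatives (adjusted p from 0.000115 to 1.00), JAG1 in 13 (1.56e-07 to 1.00), NOTCH2 in 13 (2.96e-24 to 0.959), RARB in 8 (6.38e-108 to 1.00) and CYP26B1 in 4 (5.95e-27 to 1.00). Of 70 named genes called with the replicate block, 39 passed whichever pair was left out. Genes with a few counts, such as CYP26A1, SP7 and HEY1, were removed by the default expression filter, so the paired fit with that filter gave no value for them.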

Other observations

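The Hedgehog test, the genes named in this part and the splits of the gene counts without a block were chosen after the values were seen. Transcription factors of mesenchymal cells were looked at singly, after TWIST1, SNAI2 and MSC had been seen to fall, so they say nothing about such factors as a group. In the paired edgeR fit, SIX2 went from 32.8 ± 12.3 to 14.1 ± 5.75 TPM (SD, n = 4; log2 fold change -1.25 ± 0.16 SE, adjusted p = 0.00461), HMGA2 from 34.2 ± 20.1 to 14.1 ± 6.19 TPM (-1.23 ± 0.20, adjusted p = 0.0391) and ZEB2 from 80.4 ± 18.1 to 60.6 ± 5.90 TPM (-0.40 ± 0.08, adjusted p = 0.0224). Each of the 3 was lower in 4 of 4 pairs. TWIST2, SNAI1, ZEB1 and OSR1 had log2 fold changes between -0.05 and 0.02 and adjusted p-values of 0.939 or more. Without pair 2, FOXC1 was called higher (0.90, adjusted p = 6.37e-05) and MEOX2 lower (-1.85, adjusted p = 0.0357), and neither passed over all pairs.

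Without pair 2, the paired edgeR fit also called the following genes, each chosen after its values were seen. The vitamin D receptor VDR had a log2 fold change of 1.34 ± 0.16 (adjusted p = 0.000657) and CYP24A1, the enzyme that inactivates vitamin D, of 2.47 ± 0.52 (adjusted p = 0.0250), both higher in 4 of 4 pairs. The interferon regulatory factor IRF1 had 1.99 ± 0.18, the cholesterol exporter ABCA1 1.49 ± 0.12, the protease ADAM19 1.76 ± 0.14, the kinase CAMK2A 4.69 ± 0.48 and the retinoid-responsive RARRES1 3.45 ± 0.45. Of these 7, ABCA1 alone passed over all pairs (adjusted p = 0.0305). ADAMTS1 was at 371 ± 88.3 TPM (SD, n = 3) in Wnt3a libraries 1, 3 and 4 and at 91.3 to 143 TPM with ATRA (-1.83 ± 0.24, adjusted p = 0.0322, and 0.139 over all pairs). NBPF14 had a log2 fold change of 1.28 ± 0.11 beside the 1.07 ± 0.09 of NOTCH2, and 100% of its transcript is shared with other genes, so its value is uncertain.

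GAS1 and BOC, a further Hedgehog co-receptor, were lower in the paired edgeR fit, BOC by -0.46 ± 0.10 on the log2 scale (adjusted p = 0.0271, and 0.167 without pair 2, lower in 4 of 4 pairs). CDON, another co-receptor, went the other way, with 0.41 ± 0.16 over all pairs (adjusted p = 0.257) and a call without pair 2 (0.63, adjusted p = 0.0200). Lower Hedgehog pathway output may go with the first 2 genes. Of the 3 target genes PTCH1, GLI1 and HHIP, 0 passed over all pairs. Their log2 fold changes were -1.10 ± 0.36, -0.42 ± 0.45 and -0.36 ± 0.23, with adjusted p-values from 0.207 to 0.772. PTCH1 passed without pair 2 (-1.52, adjusted p = 0.00379), so the hypothesis is neither excluded nor shown.

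Regrouping the libraries bore on the counts of calls. Without a block the real split of the 8 libraries had 0 calls, in total and in either direction. Any of the 35 splits into 4 and 4 reaches 0, so their number says nothing about chance. The highest other split had 120 calls, with 72 in one direction, and the highest in the other direction was 50. That split set donors 1 and 3 against 2 and 4, and the other 2 splits that kept donors whole gave 25 and 108, while all remaining splits gave 0. This points to donor as the main structure of the samples. For lists without a block, 25 of 35 splits had at least the 4 lists of the real split, up to 9, so chance is not excluded. With the block, the 8 splits that part every pair are too few for a share under 0.05. The real split had 400 calls and the highest other 0, with 1 split as large, and 5 lists against 3, again 1 split as large. Without pair 2 there are 4 such splits, with 575 calls in the real split and 0 in the highest other, 1 split as large.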
